A study of Mus musculus with 16 samples.

How the data were processed

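RNA was measured in 16 libraries from C57BL/6 wild-type mice. Per the labels, the cells were bronchoalveolar lavage cells (BALF), peritoneal lavage cells (PLF), bone marrow derived macrophages (BMDM) and ex vivo cultured alveolar macrophages (mexAM) of mice 1, 2 and 4, plus cultured alveolar macrophages of 2 lavage pools at 2 passages each. Per the labels' protocols, total RNA was isolated with the RNeasy Micro kit, and 150 ng of it went into QuantSeq 3' FWD libraries with a module for unique molecular identifiers (UMIs) and 15 cycles of amplification. Integrity was assessed on a Bioanalyzer, and the libraries were sequenced as 65 bp single-end reads on a HiSeq4000. The mouse numbers were taken as the same animal across cell types, per the labels.

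The authors' deposited files hold raw counts of reads per gene, 1 file per library, with 47643 Ensembl gene identifiers and 5 lines that name no gene. The unit was checked on the values: all are whole numbers, and no pair of files was identical. The genome build was GRCm38 (mm10) per the labels. Aligner, counting program, annotation release and whether reads were collapsed by UMI are not given in the sources used here. Intervals and floors therefore cover counting error only. Gene names and positions were taken from GENCODE release M21, which names 47224 of the identifiers. The other 419 held 8722 counts in all libraries (0.0338%) and stayed in the fits without a name. A total of 20730 genes had any count. The 5 lines without a gene were used only as quality measures: reads outside genes made up 10.6% to 29.9% and ambiguous reads 0.451% to 0.625% of the counted reads.

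Counts in genes ranged from 827791 to 2884679 per library. The 10 most counted genes took 16.9% to 32.0% of a library. Between replicate libraries the spread exceeded counting error, with a chi-square per degree of freedom of 2.64 to 26.6 per pair. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% exact (Clopper-Pearson) binomial interval of the counts.

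Genes were filtered with filterByExpr, scaled by TMM and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3. The 6 comparisons among BALF, PLF, BMDM and mexAM came from 1 fit of 12 libraries (10011 genes, 8 residual degrees of freedom). For the comparisons of pool cultures with mexAM, BALF and BMDM, the 2 passages of each pool were summed, since they are not independent, in a fit of 14 columns (10602 genes, 9 residual degrees of freedom). The later passage was compared with the earlier one in a fit of 16 libraries (10527 genes, 10 residual degrees of freedom). F tests were adjusted by Benjamini-Hochberg over all genes of a comparison, at a threshold of 0.05. The standard error of a log2 fold change was its size divided by the root of F. CPM are counts scaled to a common library total, and those given beside fold changes used TMM-scaled totals. Log2 CPM used a prior count of 2.

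The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. The 39 gene lists covered macrophage types, metabolic and immune programmes, other cell types and RNA quality, and all but Ear3 and Ahsp were matched to the files. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, and again with an estimated correlation. List p-values were adjusted over the 39 lists. Members were also counted with p-values adjusted over the list alone. Genes named in each comparison were the 5 largest called changes in each direction with a mean of at least 50 CPM in the higher group and the same direction in every mouse, or groups that did not overlap. Predicted genes, pseudogenes and immunoglobulin and T cell receptor segments were left out of these. Up to 4 called members of each list with at least 10 CPM in the higher group, and 15 macrophage genes in every comparison, were named as well, among them Pparg, Siglecf, Car4, Itgax, Marco, Chil3, Fabp1, Gata6, Adgre1, Csf1r, Itgam, Mrc1, Cx3cr1 and Mki67. The text gives a selection of the genes the rule names. Haemoglobin, Scgb1a1, Gm42418, Il1b, Cd79a, Ighm, Bhlhe41, Cish, Csn2 and Malat1 levels were chosen after their values were seen. The naming rule also gives Cish, Scgb1a1 and haemoglobin genes, for pool cultures against BALF.

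Similarity was the Spearman correlation of log2 CPM of each mexAM library with the mean of another group, tested by an exact two-sided sign-flip test over mice, which with 3 mice cannot give a p below 0.25. The pairs of log2 changes were compared with Pearson's r across genes, without a p-value.

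Whether mice pair the libraries was checked on deviations from group means. Same-mouse correlations between cell types ran from -0.118 to 0.220 (median -0.0207), and 2 of 18 exceeded 0.1. Both were between BALF and PLF, at 0.220 in mouse 1 and 0.132 in mouse 4. The same check gave 0.0570 for the passages of pool 1. Mouse and pool were used as a block only among the alternatives. With mouse as a block BALF against PLF called 3885 genes in place of 4031.

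The fits were tested on simulated data with 200 changed genes and the depth and spread of these libraries. The real comparisons called 1 to 5800 genes. The cut-off of the adjustment depends on how many genes change, so recovery in them may differ. In the order of the report's comparisons, a 4-fold change was recovered for 75.4%, 93.7%, 79.0%, 90.6%, 80%, 76.2%, 74.2%, 78.5%, 84.1% and 42.2% of genes. A 2-fold change was recovered for 31.8%, 28.1%, 24.2%, 20.3%, 35.4%, 34.4%, 23.4%, 16.7%, 24.6% and 1.52%, and a 1.5-fold change for 0 to 6.15%. False calls were 5 of 77, 8 of 88, 6 of 73, 5 of 80, 3 of 81, 8 of 80, 3 of 69, 2 of 65, 7 of 80 and 0 of 28. A list raised 1.5-fold was found in each comparison, also with an estimated correlation (highest adjusted p = 0.0382), and 1 other list was called, in pool cultures against BMDM. The simulated genes were drawn independently, so these list results do not cover lists whose genes move together. With no group effect the correlation of the contrasts that share no library was -0.0143.

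The alternatives were the DESeq2 1.42.0 Wald test, RLE size factors, library totals alone, no filter on low counts, a minimum of 10 CPM, mouse and pool as blocks, fits of fewer or more libraries, a 2-fold minimum, unsummed passages, fry in place of camera, and leaving out each library, mouse or pool. Where this left 1 library in a group, that library was assumed to vary like the other groups. Added after the data were seen were fits without ribosomal RNA features, with BALF of mouse 1 alone, with each passage alone and with thinned libraries. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main comparisons. Sequence reads were not analysed here.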

Results

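RNA was measured in 16 libraries of lavage cells and cultured macrophages from C57BL/6 wild-type mice by QuantSeq, a method that reads the 3' ends of messenger RNA. BALF denotes cells from bronchoalveolar lavage, which in an unchallenged mouse are mainly alveolar macrophages. PLF denotes cells from peritoneal lavage, BMDM are macrophages grown from bone marrow, and mexAM are murine alveolar macrophages kept in culture. Each of these 4 groups held 3 libraries, from mice 1, 2 and 4. A further 4 libraries came from cultured alveolar macrophages of 2 lavage pools, pool 1 at passages 8 and 13 and pool 2 at passages 5 and 10. The passage of the mexAM cultures of single mice was not given in the sources used here. Counts assigned to genes ranged from 827791 to 2884679 per library. BALF held 1664635, 985582 and 1295736 counts, BMDM 2068473, 1458341 and 1631685, mexAM 1721856, 2055082 and 2427996, and PLF 1540840, 1121293 and 1622236, for mice 1, 2 and 4. Pool 1 held 1038002 counts at passage 8 and 1490455 at passage 13, and pool 2 held 827791 at passage 5 and 2884679 at passage 10. At the lowest of these totals 1 count equals 1.21 CPM, the unit of counts scaled to a common library total. Changes are log2 fold changes ± the standard error of the edgeR quasi-likelihood fit, levels are mean CPM ± SD, and both rest on 3 mice per group unless stated. A gene is called changed when its Benjamini-Hochberg adjusted p was under 0.05. The p-values use 1 estimate of the spread per gene, shared by all groups of a fit. For the pool and passage comparisons that spread comes mostly from the groups of mice 1, 2 and 4.

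The libraries fell into 4 positions by cell type. Principal component 1 held 55.2% of the variance of log2 CPM and component 2 held 16.4%. The rank correlation of mexAM libraries with the mean of BALF was 0.865 ± 0.0132 (SD, n = 3), against 0.702 ± 0.0123 with BMDM and 0.618 ± 0.0115 with PLF. The other mexAM libraries gave 0.968 ± 0.00739. The difference between the correlation with BALF and that with BMDM was 0.163 ± 0.00151 and positive in 3 of 3 mice. It was 0.0522 when genes with few counts were kept in and 0.207 among genes of at least 10 CPM. The difference had an exact two-sided sign-flip p of 0.25, the smallest that 3 mice allow. The 4 pool libraries correlated at 0.943 to 0.966 with mexAM, at 0.868 to 0.877 with BALF and at 0.707 to 0.722 with BMDM. These are correlations across genes, which are not independent replicates.

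**Figure D1:**
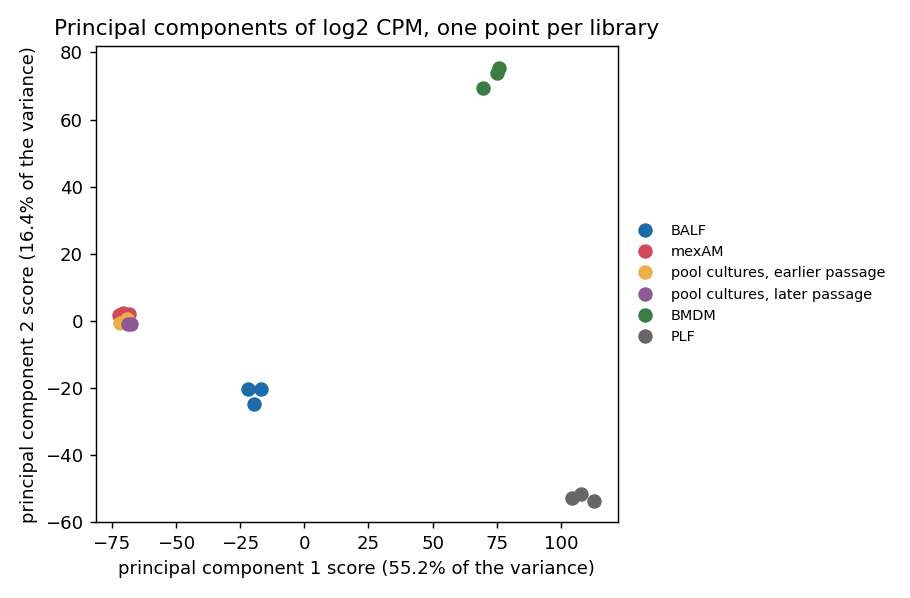
Scores of the 16 libraries on principal components 1 (horizontal) and 2 (vertical) of log2 CPM, 1 point per library, coloured by group. Components 1 and 2 held 55.2% and 16.4% of the variance, and the mexAM and pool points lie together, apart from BALF, BMDM and PLF.

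Signs of RNA quality and of other cells differed between the groups. The share of counted reads outside annotated genes was 29.0% ± 1.22 in PLF, 24.7% ± 3.74 in BMDM, 20.5% ± 0.809 in BALF and 14.2% ± 1.16 in mexAM. In the pools it was 11.5% at the earlier and 10.9% at the later passages. Transcripts of the mitochondrial genome took 14.2% ± 2.10 of counts in BALF, 10.7% ± 1.21 in mexAM, 10.5% ± 0.506 in PLF and 9.91% ± 0.837 in BMDM. The pools held 14.4% ± 2.85 at the earlier and 14.4% ± 0.991 at the later passages (SD, n = 2), above mexAM. Mitochondrial ribosomal RNA took 9.12% to 11.05% of counts in the pool libraries, 8.81% to 11.21% in BALF and 5.81% to 6.79% in mexAM. It took 6.87% to 8.45% in BMDM and 5.19% to 8.47% in PLF. The BALF libraries of mice 2 and 4 held 297 and 492 CPM of Hbb-bs (haemoglobin) and 14.7 and 27.0 CPM of Scgb1a1 (a club cell secretory protein), against 23.6 and 0.694 CPM in mouse 1. Gm42418, a ribosomal RNA locus, was at 138485, 37876 and 36760 CPM in PLF of mice 1, 2 and 4, at 127744, 47556 and 158579 CPM in BALF and at 54084, 114916 and 120582 CPM in BMDM. PLF of mouse 1 held 78.1 CPM of Il1b against 573 and 415 in the other PLF libraries. B cell list transcripts summed to 4337 ± 189 CPM in PLF, 939 ± 63.0 in BALF, 886 ± 83.6 in mexAM and 235 ± 20.1 in BMDM. A single gene, Bhlhe41, held 866 ± 54.3 CPM of this sum in BALF and 807 ± 109 in mexAM, while Cd79a, a B cell receptor subunit, had 0 counts in both.

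**Figure D2:**
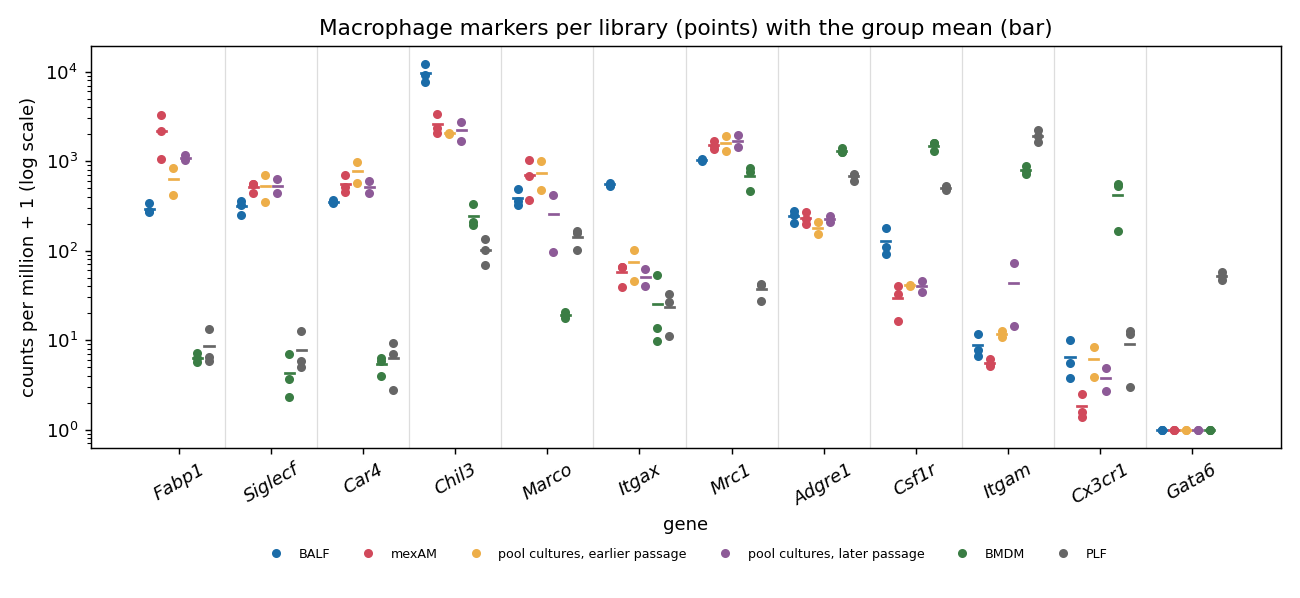
CPM + 1 on a logarithmic axis for 12 macrophage genes (horizontal), 1 point per library and a bar at the mean of each group. Fabp1, Siglecf and Car4 average 294 to 2170 CPM in BALF, mexAM and pool cultures and 3.29 to 7.52 CPM in BMDM and PLF, while Gata6 is at 0 outside PLF.

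The comparison of mexAM with BALF asks which genes alveolar macrophages in culture express differently from freshly lavaged lung cells. Several genes close to silent in BALF were abundant in culture. Vipr2, a receptor for vasoactive intestinal peptide (ENSMUSG00000011171, chromosome 12, 116077726 to 116146261, plus strand, GRCm38), had 124 ± 67.8 against 0 ± 0 CPM, at least 135-fold higher. Cyp4a12b, a fatty acid hydroxylase (ENSMUSG00000078597, chromosome 4, 115411624 to 115439034, plus strand), changed by +8.76 ± 0.45 (665 ± 268 against 1.45 ± 1.26 CPM) and its close paralog Cyp4a12a by +8.48 ± 0.59. Necab1 and Slc32a1 were higher by ratios of 254 (95% interval 45.4 to 10062) and 244 (95% interval 43.6 to 9673). In the other direction, Pdlim1, a cytoskeletal adaptor, was lower by a ratio of 298 (95% interval 82.0 to 2475), and Cd2, an adhesion receptor, changed by -7.70 ± 0.39 (1.05 ± 0.998 against 217 ± 32.4 CPM). The heat shock genes Hspa1a and Hspa1b changed by -7.43 ± 0.57 and -7.34 ± 0.70, and Hbb-bs by -7.19 ± 1.01. How reads divided between these close paralogs is uncertain.

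Genes used to recognise alveolar macrophages moved both ways. Of 36 alveolar macrophage identity genes tested, 7 rose, 7 fell and 22 were not called (9 rose and 7 fell adjusted over the list alone). The list as a set was not called (camera adjusted p = 0.709), with a median of +0.24 and a mean of -0.30. The list summed to 35210 ± 1348 CPM in BALF, 30485 ± 1634 in mexAM, 9173 ± 3732 in BMDM and 4594 ± 1096 in PLF. Fabp1, a fatty acid binding protein (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023, plus strand), rose (+2.88 ± 0.34, 2166 ± 1097 against 294 ± 41.9 CPM). Itgax, the integrin CD11c, fell (-3.29 ± 0.51, 56.3 ± 15.7 against 547 ± 27.0 CPM), as did Chil3, a chitinase-like protein (-1.89 ± 0.29, 2596 ± 681 against 9613 ± 2333 CPM). Siglecf, a sialic acid binding lectin of alveolar macrophages, was at 517 against 311 CPM (+0.73 ± 0.26, adjusted p = 0.0426). Its call was lost without any 1 BALF library (+0.85, +0.76 and +0.60) and without mexAM of mouse 1 (+0.68) or mouse 2 (+0.67). Car4 was at 559 against 348 CPM (+0.68 ± 0.24, adjusted p = 0.0387), a call lost without any 1 BALF library (0.66 to 0.71) and without mexAM of mouse 2 (+0.73) or mouse 4 (+0.48). The scavenger receptor Marco rose (+0.85 ± 0.30, adjusted p = 0.0417), and its call was lost without BALF of mouse 1 (+0.72) or mouse 2 (+0.78) and without mexAM of mouse 1 (+0.85) or mouse 2 (+0.44). Pparg, the nuclear receptor needed for alveolar macrophage development, was not called (-0.32 ± 0.48, adjusted p = 0.662, 72.1 ± 59.3 against 89.6 ± 25.6 CPM). Neither were the pan-macrophage genes Adgre1 (-0.07, adjusted p = 0.812) and Mrc1 (+0.56, adjusted p = 0.0706) or the integrin Itgam (-0.72, adjusted p = 0.158). Csf1r, the receptor for macrophage colony stimulating factor, fell (-2.15 ± 0.30). Cx3cr1 was not called (-2.55, adjusted p = 0.103), and Gata6 was listed at 0 counts in both groups.

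Genes of cholesterol biosynthesis and fatty acid oxidation rose in culture, while other lipid genes moved both ways. Of 23 cholesterol biosynthesis genes, 19 rose and 0 fell, and the same numbers held adjusted over the list alone. Among them were the sterol enzymes Lss (+2.35 ± 0.26) and Tm7sf2 (+3.67 ± 0.50), and the median of the list was +1.22. Its camera adjusted p was 1.32e-08, and adjusted p = 0.297 with an estimated correlation. For fatty acid oxidation 14 of 22 rose and 0 fell (14 and 0 adjusted over the list alone), including Acaa2 (+2.14 ± 0.23), Eci1 (+1.70 ± 0.28) and Acadvl (+1.47 ± 0.24). Camera gave an adjusted p of 8.98e-05, and adjusted p = 0.297 with an estimated correlation. Of 22 PPARgamma target and lipid storage genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), among them Plin1, a lipid droplet coat protein (+5.15 ± 0.36). The set had a camera adjusted p of 0.00880, and adjusted p = 0.508 with an estimated correlation. The fatty acid desaturase Scd1 rose (+4.73 ± 0.45), as did fatty acid synthase, Fasn (+3.34 ± 0.28), while the cholesterol exporter Abca1 fell (-2.48 ± 0.38). These genes belong to the LXR targets, of which 5 of 15 rose and 3 fell (7 and 4 adjusted over the list alone), a set that was not called (camera adjusted p = 0.331).

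Proliferation and respiration genes also rose. Among 38 cell cycle genes 21 rose and 1 fell (24 and 1 adjusted over the list alone), including the replication helicase Mcm6 (+2.23 ± 0.27) and the proliferation marker Mki67 (+1.29 ± 0.29, 104 ± 9.77 against 42.7 ± 19.1 CPM). The camera adjusted p was 1.1e-06, and adjusted p = 0.516 with an estimated correlation. Of 46 oxidative phosphorylation genes 21 rose and 0 fell (23 and 0 adjusted over the list alone), among them Sdha (+1.10 ± 0.19). That set had camera adjusted p = 7.6e-05, adjusted p = 0.508 with an estimated correlation.

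Antigen presentation genes fell. Of 14 MHC class II presentation genes 8 fell and 1 rose (8 and 1 adjusted over the list alone). H2-Aa changed by -5.08 ± 0.44 (5.44 ± 0.455 against 187 ± 13.5 CPM), the invariant chain Cd74 by -5.00 ± 0.53 and the costimulatory ligand Cd86 by -4.47 ± 0.50. The median was -3.16, or -2.74 with genes at 0 counts in 1 group set to their bound, with camera adjusted p = 3.99e-04, adjusted p = 0.477 with an estimated correlation. In MHC class I presentation 7 of 15 fell and 0 rose (9 and 0 adjusted over the list alone), for example B2m (-1.14 ± 0.22) and Pdia3 (-1.28 ± 0.18). This list had camera adjusted p = 0.00880, adjusted p = 0.297 with an estimated correlation. Beside these, 6 of 12 dendritic cell genes fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.132). That list summed to 633 ± 19.4 CPM in BALF and 336 ± 40.7 in mexAM.

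Stress, matrix and inflammatory genes fell as well. Of 22 oxidative stress response genes 10 fell and 3 rose (11 and 4 adjusted over the list alone), with camera adjusted p = 0.00411, adjusted p = 0.496 with an estimated correlation. Haem oxygenase, Hmox1, changed by -5.28 ± 0.39 (279.7 ± 24.1 against 10892 ± 3034 CPM), Srxn1 by -4.81 ± 0.42 and Slc7a11 by -4.39 ± 0.29. Among 21 matrix genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), including fibronectin, Fn1 (-5.62 ± 0.36), Timp2 (-5.81 ± 0.31) and Tgfbi (-3.69 ± 0.49). Camera gave 5.57e-06 for matrix genes, and adjusted p = 0.297 with an estimated correlation. Inflammatory genes fell for 9 of 22 and rose for 0 (9 and 0 adjusted over the list alone), for example Cxcl3 (-4.07 ± 0.54). Their set had camera adjusted p = 0.00880, adjusted p = 0.732 with an estimated correlation.

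Genes of other macrophages and of lung epithelium were lower in culture. Of 29 peritoneal macrophage genes 8 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -1.46, or -0.87 with bounds, and camera adjusted p = 0.0107, adjusted p = 0.477 with an estimated correlation. Of 29 genes of bone marrow derived macrophages and monocytes 10 fell and 2 rose (10 and 2 adjusted over the list alone), for example Apoe (-2.62 ± 0.34) and the lipopolysaccharide receptor Cd14 (-2.28 ± 0.32). This set had camera adjusted p = 0.0109, adjusted p = 0.297 with an estimated correlation. Lung epithelium genes fell for 3 and rose for 1 of 5 (3 and 1 adjusted over the list alone), with camera adjusted p = 0.0158, adjusted p = 0.297 with an estimated correlation. Epcam was lower by a ratio of 252 (95% interval 44.5 to 10019.9) and Napsa changed by -4.30 ± 0.36.

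The other lists were not called as sets in this comparison. For each, the numbers that rose and fell are followed by those adjusted over the list alone in parentheses and by the camera adjusted p. Pan-macrophage markers had 2 and 4 of 18 (2 and 4), 0.239, and TGFbeta responsive genes 3 and 7 of 20 (5 and 11), 0.0824. GM-CSF signalling had 2 and 2 of 16 (2 and 2), 0.692, and immediate early genes 4 and 7 of 26 (4 and 7), 0.0718. Interferon stimulated genes had 1 and 4 of 29 (1 and 2), 0.331, and complement 2 and 6 of 15 (2 and 6), 0.234. Scavenger receptors had 6 and 5 of 25 (8 and 7), 0.609, and lysosome genes 6 and 7 of 36 (7 and 7), 0.686. Glycolysis had 3 and 1 of 16 (5 and 1), 0.331, and hypoxia response 5 and 0 of 16 (5 and 0), 0.0837. Leukotriene and prostaglandin synthesis had 4 and 4 of 18 (5 and 5), 0.917, and actin and adhesion 4 and 7 of 23 (4 and 7), 0.415. Cyclin dependent kinase inhibitors and p53 targets had 3 and 4 of 18 (4 and 4), 0.807, with Cdkn2a at +4.23 ± 0.50 and Cdkn2b at -3.10 ± 0.45. Among markers of other cells, B cells had 1 and 1 of 19 (0 and 0), 0.686, T and NK cells 1 and 1 of 13 (1 and 1), 0.807, and neutrophils 2 and 0 of 14 (2 and 0), 0.709. Eosinophils had 1 and 1 of 7 (1 and 1), 0.709, mast cells 0 and 1 of 9 (0 and 0), 0.578, mesothelium and fibroblasts 1 and 0 of 4 (1 and 0), 0.436, and erythroid cells and platelets 2 and 2 of 5 (2 and 2), 0.917. Mitochondrially encoded transcripts had 0 and 1 of 10 (0 and 1), 0.295, nuclear retained RNA 0 and 2 of 5 (0 and 2), 0.606, and ribosomal proteins 3 and 2 of 46 (2 and 1), 0.686. Median, mean and test differed in sign for the alveolar macrophage and leukotriene lists here, and in every comparison such differences occurred only in lists that were not called.

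In total 3007 of 10011 genes were called between mexAM and BALF, 1522 higher and 1485 lower in mexAM, and 2042 of them changed at least 2-fold. With library totals alone as the scaling the median of all genes moved to 0.22 and 67.4% of calls were higher in mexAM instead of 50.6%. With BALF of mouse 1 alone, the library low in haemoglobin, 1318 genes were called. Of the 13 lists called by camera with its preset correlation, 0 held with an estimated correlation.

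**Figure D3:**
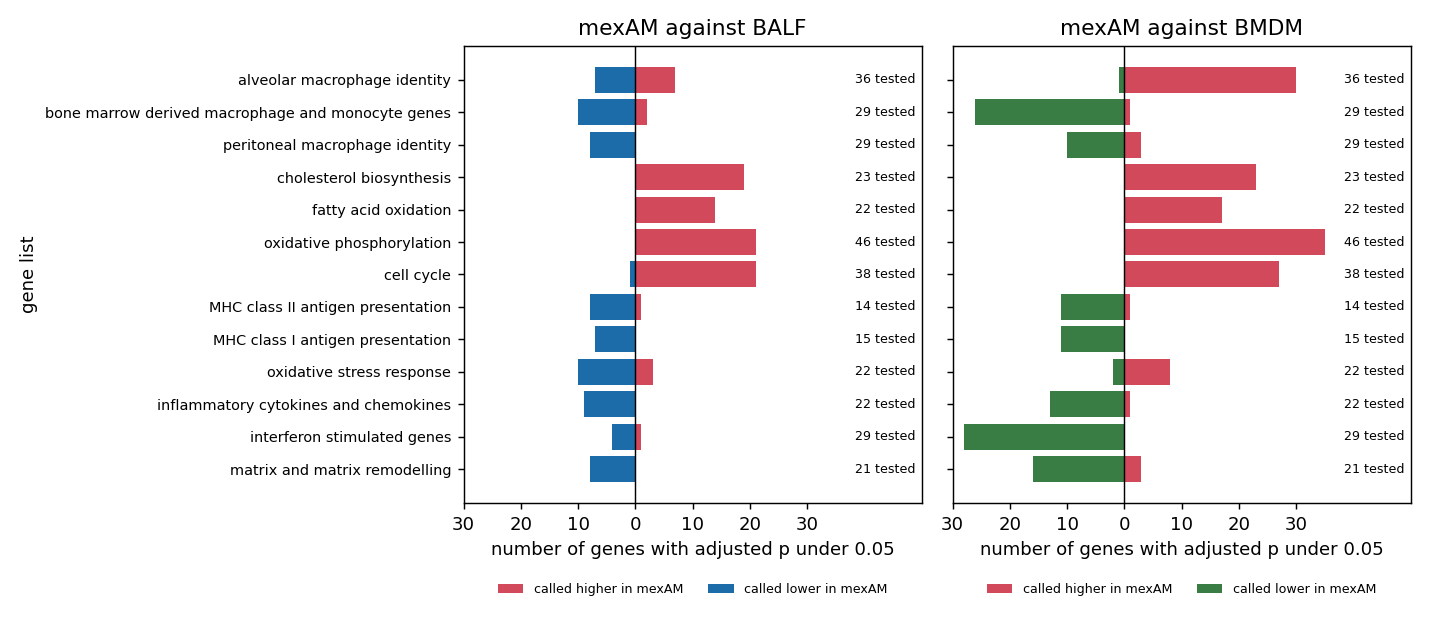
Number of genes called higher (right of 0) or lower (left of 0) in mexAM against BALF (left panel) and BMDM (right panel) for 13 gene lists, with the number tested at the right. Alveolar macrophage identity genes split 7 and 7 against BALF and 30 and 1 against BMDM, while cholesterol genes were called higher for 19 and 23 of 23.

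The comparison of mexAM with BMDM sets a pair of cultured macrophages side by side. The culture media of both are not given in the sources used here, so in this comparison and in that of the pool cultures with BMDM the origin of the cells is not separated from their medium. Alveolar macrophage genes were higher in mexAM and monocyte and bone marrow macrophage genes lower. Siglecf (ENSMUSG00000039013, chromosome 7, 43351341 to 43359531, plus strand) changed by +7.34 ± 0.39 (517 ± 68.7 against 3.26 ± 2.33 CPM), Fabp1 by +8.63 ± 0.47 (2166 ± 1097 against 5.34 ± 0.808 CPM), the carbonic anhydrase Car4 by +6.98 ± 0.34, the scavenger receptor Marco by +5.27 ± 0.37 and Chil3 by +3.43 ± 0.31. Lipf, a gastric lipase, was at 131 ± 4.22 against 0 ± 0 CPM, at least 240.5-fold higher, and Vipr2, Fam189a2 and the adaptor Grb7 were at least 217-fold, 173-fold and 150.3-fold higher. Tmem176b was at 0 ± 0 against 448 ± 136 CPM, at least 967-fold lower, and Fcrls and the scavenger receptor Stab1 were at least 781-fold and 591-fold lower. The complement gene C1qc changed by -10.23 ± 0.41 (0.976 ± 0.891 against 1242 ± 65.5 CPM), the integrin Itgam by -7.39 ± 0.28 (4.56 ± 0.527 against 786 ± 91.7 CPM), the chemokine receptor Cx3cr1 by -8.88 ± 0.71, Csf1r by -5.69 ± 0.33 and Adgre1 by -2.51 ± 0.20.

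Of 36 alveolar macrophage identity genes 30 were higher and 1 lower in mexAM (31 and 1 adjusted over the list alone), with a median of +3.67 and camera adjusted p = 1.6e-15, adjusted p = 0.00997 with an estimated correlation. Of 29 bone marrow macrophage and monocyte genes 26 were lower and 1 higher (26 and 1 adjusted over the list alone), including Pf4 (-9.89 ± 0.42) and Apoe (-9.70 ± 0.39). The median was -7.39, or -6.75 with bounds, and this set had camera adjusted p = 2.86e-16, adjusted p = 0.00340 with an estimated correlation. All 23 cholesterol genes were higher, also adjusted over the list alone, among them Hmgcs1 (+4.86 ± 0.24, 1513 ± 117 against 52.0 ± 15.4 CPM) and Fdps (+4.64 ± 0.29). They had camera adjusted p = 1.6e-15, adjusted p = 0.0311 with an estimated correlation.

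Of the lists whose call was lost with an estimated correlation, the largest median change stood in interferon stimulated genes, with 28 of 29 lower and 0 higher (28 and 0 adjusted over the list alone), such as Ifitm3 (-9.42 ± 0.41). Their median was -6.93, or -5.64 with bounds, with camera adjusted p = 8.08e-14, adjusted p = 0.280 with an estimated correlation. PPARgamma targets were higher for 18 and lower for 1 of 22 (19 and 1 adjusted over the list alone), with Angptl4 at +4.88 ± 0.42 and camera adjusted p = 9.73e-08, adjusted p = 0.103 with an estimated correlation. MHC class II genes were lower for 11 and higher for 1 of 14 (11 and 1 adjusted over the list alone), with H2-Aa at -5.96 ± 0.45 and camera adjusted p = 5.1e-04, adjusted p = 0.296 with an estimated correlation. For the other called lists the numbers higher and lower, followed by those adjusted over the list alone, were 17 and 0 of 22 (17 and 0) for fatty acid oxidation, 27 and 0 of 38 (31 and 0) for the cell cycle and 35 and 0 of 46 (39 and 0) for oxidative phosphorylation. Camera gave adjusted p of 1.96e-07, 1.5e-06 and 1.43e-07, and with an estimated correlation adjusted p = 0.103, 0.428 and 0.288. Lower as sets were matrix (3 and 16 of 21 (3 and 16)), inflammatory (1 and 13 of 22 (1 and 13)), complement (2 and 7 of 15 (3 and 9)), MHC class I (0 and 11 of 15 (0 and 11)), neutrophil (2 and 12 of 14 (2 and 12)) and dendritic cell genes (2 and 9 of 12 (2 and 9)). Their camera adjusted p were, in that order, 9.03e-06, 0.00171, 0.00317, 0.00116, 1.87e-05 and 0.00369. With an estimated correlation adjusted p = 0.223, 0.570, 0.103, 0.140, 0.251 and 0.288. Neutrophil genes summed to 646 ± 212 CPM in mexAM and 3693 ± 1898 in BMDM. Eosinophil genes, a list that holds Siglecf, were higher (4 and 1 of 7 (4 and 2)), with camera adjusted p = 0.0483, adjusted p = 0.282 with an estimated correlation.

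Some markers were less clear. Pparg was higher (+1.52 ± 0.51, adjusted p = 0.0280), a call lost without BMDM of mouse 1 (+1.43) or mouse 2 (+1.41), without mexAM of mouse 2 (+0.73) and with mouse as a block (+1.38). Itgax was not called (+1.23 ± 0.53, adjusted p = 0.0761). Altogether 4462 genes were called, 2157 higher and 2305 lower in mexAM, 3210 of them by at least 2-fold. Of 16 lists called, 3 held with an estimated correlation, namely alveolar macrophage identity, bone marrow macrophage and monocyte genes and cholesterol biosynthesis.

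Against PLF, the peritoneal cells, mexAM held less RNA of peritoneal macrophage genes and more of alveolar macrophage, cholesterol and fatty acid oxidation genes. Gata6, the transcription factor of peritoneal macrophages (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635, plus strand), was at 0 ± 0 against 51.0 ± 5.66 CPM, at least 106-fold lower. The lipoxygenase Alox15 was at least 1641-fold lower, Retnla, a secreted resistin-like protein, lower by a ratio of 4931 (95% interval 1365 to 40729), and Itgam changed by -8.66 ± 0.29. In the other direction Fam189a2 and Necab1 were at least 139-fold and 109-fold higher. Siglecf changed by +6.31 ± 0.37, Car4 by +6.77 ± 0.34, Pparg by +3.72 ± 0.65, the mannose receptor Mrc1 by +5.43 ± 0.28 and Fabp1 by +8.23 ± 0.46. Of 29 peritoneal macrophage genes 26 were lower and 1 higher (27 and 1 adjusted over the list alone), including Selp, at least 601-fold lower. The median was -9.29, or -8.20 with bounds, with camera adjusted p = 3.09e-16, adjusted p = 0.00799 with an estimated correlation. Of 36 alveolar macrophage genes 29 were higher and 3 lower (29 and 3 adjusted over the list alone), with camera adjusted p = 5.34e-10, adjusted p = 0.0164 with an estimated correlation.

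Further lists are given as numbers higher and lower in mexAM, followed by those adjusted over the list alone in parentheses. Cholesterol genes had 23 and 0 of 23 (23 and 0) and fatty acid oxidation 21 and 0 of 22 (21 and 0), with camera adjusted p of 2.6e-12 and 4.37e-09, and adjusted p = 0.0227 and 0.0341 with an estimated correlation. Bone marrow macrophage and monocyte genes had 5 and 20 of 29 (5 and 21), with camera adjusted p = 5.65e-06, adjusted p = 0.0220 with an estimated correlation. Complement genes had 4 and 11 of 15 (4 and 11), with camera adjusted p = 2.32e-05, adjusted p = 0.0164 with an estimated correlation. Markers of other cells in the peritoneal lavage were lower in mexAM. B cell genes had 2 and 17 of 19 (2 and 17), with Cd79b and Pax5 at least 339.5-fold and 267-fold lower. T and NK cell genes had 1 and 12 of 13 (1 and 12), and mast cell genes had 0 and 9 of 9 (0 and 9) and summed to 2089 ± 99.0 CPM in PLF and 1.70 ± 0.813 in mexAM. For B, T and NK and mast cells the camera adjusted p were 3.36e-10, 4.51e-08 and 9.61e-09, and adjusted p = 0.0164, 0.00799 and 0.00799 with an estimated correlation. These 9 lists held their call with an estimated correlation, of 21 called.

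The other 12 called lists did not. Inflammatory genes had 0 and 21 of 22 (0 and 21), MHC class II 0 and 11 of 14 (0 and 11), interferon stimulated genes 0 and 24 of 29 (0 and 25), MHC class I 1 and 9 of 15 (1 and 9), dendritic cell genes 2 and 10 of 12 (2 and 10) and immediate early genes 3 and 18 of 26 (3 and 19), all lower as sets. Their camera adjusted p were, in that order, 4.45e-08, 5.24e-07, 1.87e-07, 0.0254, 9.49e-04 and 0.00847. With an estimated correlation adjusted p = 0.275, 0.13, 0.386, 0.262, 0.232 and 0.396. Matrix genes (3 and 13 of 21 (3 and 13)) and ribosomal proteins (0 and 25 of 46 (0 and 28)) were also lower, with camera adjusted p of 0.00496 and 3.57e-04, and adjusted p = 0.386 and 0.387 with an estimated correlation. Fn1 changed by -10.40 ± 0.41 and Cd14 by -5.77 ± 0.35. Higher were PPARgamma targets (19 and 1 of 22 (19 and 1)), the cell cycle (33 and 0 of 38 (34 and 0)), lysosome genes (23 and 6 of 36 (23 and 6)) and oxidative phosphorylation (41 and 0 of 46 (42 and 0)). Their camera adjusted p were 4.51e-08, 4.65e-07, 9.49e-04 and 1.14e-08, and adjusted p = 0.0612, 0.386, 0.327 and 0.232 with an estimated correlation. Altogether 5800 genes were called, 2841 higher and 2959 lower, 4285 of them by at least 2-fold.

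BALF against BMDM compares lung cells that were not cultured with cultured bone marrow macrophages, so origin and culture differ together. Siglecf changed by +6.60 ± 0.39 (311 ± 56.8 against 3.26 ± 2.33 CPM), Car4 by +6.30 ± 0.34, Itgax by +4.51 ± 0.55, Chil3 by +5.32 ± 0.34 and Fabp1 by +5.74 ± 0.44, all higher in BALF. Cidec, a lipid droplet protein, and Clmn were at least 128-fold and 94.6-fold higher, and Hmox1 changed by +4.95 ± 0.38 and the cystine transporter Slc7a11 by +5.79 ± 0.31. Itgam changed by -6.67 ± 0.28, C1qc by -7.95 ± 0.36, the transcription factor Maf by -8.77 ± 0.39 and Adgre1 by -2.43 ± 0.20, all lower in BALF. Rnf150, Blnk and the interferon-induced Ifit2 were at least 168-fold, 116-fold and 108-fold lower. Mki67 was not called (+0.72 ± 0.31, adjusted p = 0.0758).

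Of 36 alveolar macrophage identity genes 32 were higher and 2 lower in BALF (32 and 2 adjusted over the list alone), with a median of +4.67 and camera adjusted p = 2.87e-20, adjusted p = 0.00367 with an estimated correlation. Of 29 bone marrow macrophage and monocyte genes 26 were lower and 1 higher (26 and 1 adjusted over the list alone), with camera adjusted p = 2.24e-16, adjusted p = 0.00355 with an estimated correlation. Their median was -6.34, or -6.10 with bounds. Further lists are given as numbers higher and lower in BALF, followed by those adjusted over the list alone in parentheses. Cholesterol genes had 19 and 0 of 23 (19 and 0), PPARgamma targets 16 and 2 of 22 (17 and 2) and fatty acid oxidation 11 and 1 of 22 (13 and 1). Their camera adjusted p were 8.88e-09, 1.5e-05 and 0.00137, and adjusted p = 0.121, 0.202 and 0.274 with an estimated correlation. Oxidative stress genes had 13 and 1 of 22 (14 and 1) and immediate early and dissociation stress genes 16 and 1 of 26 (17 and 2), with Hspa1a at +6.33 ± 0.52. The camera adjusted p of these stress lists were 1.19e-06 and 6.5e-04, and adjusted p = 0.199 and 0.381 with an estimated correlation. Lower were interferon stimulated (0 and 28 of 29 (0 and 28)), complement (2 and 11 of 15 (2 and 11)), neutrophil (1 and 12 of 14 (1 and 12)) and dendritic cell genes (2 and 8 of 12 (2 and 8)). Camera gave 1.5e-14, 4.33e-04, 9.76e-07 and 0.0198, and with an estimated correlation adjusted p = 0.253, 0.0665, 0.202 and 0.382. Eosinophil genes (4 and 1 of 7 (4 and 1)), oxidative phosphorylation (10 and 0 of 46 (8 and 0)) and mitochondrially encoded transcripts (6 and 0 of 10 (7 and 0)) were higher. Camera gave 0.0172, 0.0275 and 0.0147 for these, and with an estimated correlation adjusted p = 0.209, 0.693 and 0.382. In all 3747 genes were called, 1818 higher and 1929 lower, 2734 of them by at least 2-fold, and 2 of 14 called lists held with an estimated correlation. Library totals alone moved the median of all genes to -0.32 and the share of calls higher in BALF from 48.5% to 30.5%, and BALF of mouse 1 alone gave 2429 calls.

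BALF against PLF compares the fresh lavage cells of lung and peritoneum. Siglecf changed by +5.58 ± 0.36, Car4 by +6.09 ± 0.34, Itgax by +4.64 ± 0.56, Chil3 by +6.60 ± 0.36, Fabp1 by +5.35 ± 0.43, Pparg by +4.04 ± 0.65 and Mrc1 by +4.87 ± 0.28, all higher in BALF. The zinc transporter Slc39a2 changed by +7.05 ± 0.34, and Adrb1, an adrenergic receptor, was higher by a ratio of 176 (95% interval 48.3 to 1462). Gata6 was at least 57.9-fold lower, the complement receptor Vsig4 at least 152-fold lower, and Itgam changed by -7.94 ± 0.29, Thbs1 by -9.75 ± 0.37 and coagulation factor F5 by -9.76 ± 0.40. The lymphocyte genes Fcmr and Bank1 were at least 257-fold and 246-fold lower.

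Of 29 peritoneal macrophage genes 26 were lower and 2 higher in BALF (27 and 2 adjusted over the list alone), with camera adjusted p = 9.88e-19, adjusted p = 0.00500 with an estimated correlation. Their median was -7.19, or -7.03 with bounds. Of 36 alveolar macrophage genes 30 were higher and 2 lower (30 and 3 adjusted over the list alone), with camera adjusted p = 3.2e-15, adjusted p = 0.00512 with an estimated correlation. For the lists that follow, the numbers adjusted over the list alone stand in parentheses after those higher and lower in BALF. Bone marrow macrophage and monocyte genes had 4 and 18 of 29 (4 and 19) and complement 2 and 10 of 15 (2 and 12), with camera adjusted p of 3.39e-06 and 1.18e-06, and adjusted p = 0.0188 and 0.00710 with an estimated correlation. B cell genes had 1 and 17 of 19 (1 and 17), T and NK cell genes 0 and 13 of 13 (0 and 13) and mast cell genes 0 and 9 of 9 (0 and 9). For these other cells camera gave 7.07e-13, 6.44e-12 and 5.87e-11, and adjusted p = 0.00710, 0.00223 and 0.00223 with an estimated correlation. The remaining lists lost their call. PPARgamma targets (19 and 2 of 22 (19 and 2)), fatty acid oxidation (19 and 0 of 22 (19 and 0)), cholesterol biosynthesis (20 and 0 of 23 (20 and 0)), lysosome genes (23 and 4 of 36 (23 and 4)), oxidative phosphorylation (25 and 0 of 46 (25 and 0)) and oxidative stress genes (12 and 3 of 22 (12 and 3)) were higher. Camera gave, in that order, 2.77e-07, 1.89e-07, 1.9e-09, 1.52e-05, 2.68e-05 and 6.66e-04. With an estimated correlation adjusted p = 0.0794, 0.0631, 0.0526, 0.221, 0.391 and 0.261. Inflammatory (0 and 18 of 22 (0 and 20)), interferon stimulated (0 and 26 of 29 (0 and 26)), MHC class II (1 and 10 of 14 (1 and 10)), dendritic cell (1 and 7 of 12 (1 and 7)) and ribosomal protein genes (0 and 21 of 46 (0 and 22)) were lower. Camera gave 1.22e-07, 1.09e-08, 9.17e-05, 0.00181 and 1.51e-04, and with an estimated correlation adjusted p = 0.300, 0.361, 0.251, 0.251 and 0.391. In all 4031 genes were called, 1952 higher and 2079 lower, 2959 of them by at least 2-fold, and 7 of 18 called lists held with an estimated correlation. Library totals alone moved the median of all genes to -0.27 and the share of calls higher in BALF from 48.4% to 33.1%.

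The difference between fresh lung and peritoneal cells was set beside that between cultured alveolar and bone marrow macrophages, as contrasts that share no library. The series held no cultured peritoneal cells, so the second contrast is not one of lung against peritoneum. Across 10011 genes the log2 changes of BALF against PLF and of mexAM against BMDM had a Pearson correlation of 0.582 and a covariance of 2.51. Within single mice the correlation was 0.491, 0.490 and 0.505. Of genes called with at least a 2-fold change in both contrasts, 1481 had the same direction, 653 higher and 828 lower on the lung side, where independent lists would share 200.04 and 278. Another 172 had opposite directions, where 471 would be shared. With the pool cultures in place of mexAM the correlation was 0.562 and the numbers were 1455 and 180. The contrasts of cultured with fresh cells, mexAM against BALF and BMDM against PLF, gave a correlation of 0.187, with 570 genes in the same direction (270 higher and 300 lower in culture, with 143 and 122 for independent lists) and 216 opposite (264). BMDM and PLF differ in origin as well as in culture.

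PLF against BMDM compares the remaining pair, of fresh peritoneal cells and cultured bone marrow macrophages. Gata6 was at least 92.8-fold higher in PLF, the phosphatidylserine receptor Timd4 and Vsig4 at least 259-fold and 244-fold higher, and Retnla changed by +10.96 ± 0.47 and Prg4, a lubricating proteoglycan, by +10.46 ± 0.46 (4225 ± 460.4 against 3.04 ± 1.32 CPM). Itgam changed by +1.27 ± 0.20, Marco by +2.96 ± 0.35 and Fn1 by +7.74 ± 0.36. Lower in PLF were Mrc1 (-4.27 ± 0.27), Cx3cr1 (-5.69 ± 0.56), Csf1r (-1.56 ± 0.27), Adgre1 (-0.98 ± 0.19), Gas6 (-6.93 ± 0.37) and Ms4a7 (-7.07 ± 0.31). Of 29 peritoneal macrophage genes 27 were higher and 0 lower (27 and 0 adjusted over the list alone), with camera adjusted p = 4.37e-27, adjusted p = 0.00212 with an estimated correlation. Their median was +6.76, or +6.63 with bounds.

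For other lists in this comparison the numbers higher and lower in PLF are followed by those adjusted over the list alone in parentheses. Bone marrow macrophage and monocyte genes had 4 and 20 of 29 (4 and 20), B cell genes 19 and 0 of 19 (19 and 0), T and NK cell genes 10 and 2 of 13 (10 and 2) and mast cell genes 9 and 0 of 9 (9 and 0). Cma1, a mast cell chymase, was higher by a ratio of 1382 (95% interval 382 to 11421). These lists had camera adjusted p of 3.07e-06, 1.03e-19, 2.79e-07 and 1.22e-12, and adjusted p = 0.0228, 0.00308, 0.00691 and 0.00212 with an estimated correlation. The rest lost their call. Immediate early (23 and 0 of 26 (24 and 0)), inflammatory (15 and 0 of 22 (15 and 0)), MHC class II (11 and 1 of 14 (11 and 1)), GM-CSF signalling (9 and 2 of 16 (10 and 2)) and ribosomal protein genes (29 and 0 of 46 (34 and 0)) were higher. Their camera adjusted p were 2.04e-07, 3.76e-06, 1.1e-05, 0.00714 and 5.75e-08, and adjusted p = 0.190, 0.357, 0.212, 0.369 and 0.212 with an estimated correlation. Lysosome (3 and 22 of 36 (3 and 23)), pan-macrophage (2 and 10 of 18 (2 and 10)), fatty acid oxidation (0 and 9 of 22 (0 and 9)), interferon stimulated (1 and 12 of 29 (1 and 12)), neutrophil (2 and 10 of 14 (2 and 10)) and mesothelium and fibroblast genes (0 and 3 of 4 (0 and 3)) were lower. Camera gave 4.46e-06, 0.00185, 0.00312, 0.00144, 6.82e-05 and 0.00345, in that order. With an estimated correlation adjusted p = 0.212, 0.190, 0.249, 0.594, 0.212 and 0.212. In all 3652 genes were called, 1806 higher and 1846 lower in PLF, 2597 of them by at least 2-fold, and 5 of 16 called lists held with an estimated correlation.

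Cultures from the lavage pools were compared with mexAM of single mice, with the 2 passages of a pool summed because they are not independent, which leaves 2 pools against 3 mice. In each sum the later passage weighs more, with 1490455 against 1038002 counts in pool 1 and 2884679 against 827791 in pool 2. The same sums were used against BALF and BMDM. Whether mice 1, 2 or 4 contributed to the pools is not given in the sources used here, so their independence of mexAM and BALF is not known. Genes of cell division were higher in the pool cultures. Cenpa, a centromere histone (ENSMUSG00000029177, chromosome 5, 30666777 to 30674830, plus strand), changed by +1.75 ± 0.21 (89.3 ± 6.78 against 26.3 ± 3.35 CPM; +0.78 and not called with the earlier passages alone), and Clic4, an intracellular chloride channel protein, by +1.65 ± 0.23 (672 ± 8.27 against 215 ± 70.4 CPM). The histone gene Hist1h2bc was lower (-2.05 ± 0.32, 67.0 ± 11.3 against 278 ± 54.1 CPM), a call lost without pool 1 (-1.89) or pool 2 (-2.23). Of 38 cell cycle genes 7 were higher and 0 lower (29 adjusted over the list alone; median +1.19; camera adjusted p = 8.52e-16, adjusted p = 0.669 with an estimated correlation). Mki67 changed by +1.28 ± 0.27 (adjusted p = 0.0355, 253 ± 24.5 against 104 ± 9.68 CPM), and its call was lost without any 1 library of either group, at 1.18 to 1.37. At the earlier passages Mki67 was at 191 CPM in pool 1 and 81.8 CPM in pool 2, against 94.8 to 116 CPM in mexAM. At the later passages it was at 255 and 314 CPM. Itgam was higher (+2.71 ± 0.45, 31.0 ± 25.6 against 4.55 ± 0.527 CPM), a call lost without pool 1 (+1.48) or mexAM of mouse 1 (+2.62) and with the earlier passages alone (+1.22). Not called were Siglecf (+0.04), Car4 (+0.10), Marco (-0.71), Chil3 (-0.26), Pparg (+0.62), Itgax (-0.04), Mrc1 (+0.22), Adgre1 (-0.09), Csf1r (+0.54) and Fabp1 (-1.14, adjusted p = 0.128).

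Of 6 nuclear retained RNAs 0 were higher and 1 lower (0 and 3 adjusted over the list alone), with camera adjusted p = 0.00114, adjusted p = 0.117 with an estimated correlation. Oxidative stress genes had 0 and 1 of 22 (0 and 2) and oxidative phosphorylation genes 0 and 0 of 46 (0 and 0) higher and lower, with the numbers adjusted over the list alone in parentheses, and both were lower as sets. Camera gave 0.00312 and 0.00114, and adjusted p = 0.860 and 0.860 with an estimated correlation. Inflammatory genes (0 and 0 of 22 (0 and 0)) were higher as a set, with camera adjusted p = 0.0312, adjusted p = 0.860 with an estimated correlation. In total 74 of 10602 genes were called, 55 higher and 19 lower, 72 of them by at least 2-fold, and 1494 had an unadjusted p under 0.05. This count moved with single libraries, to 9 without pool 1, 6 without pool 2, 28 without mexAM of mouse 1 and 48 without mexAM of mouse 4. With the passages unsummed it was 207 (94 higher and 113 lower), with the passages unsummed and mouse and pool as blocks 198 (97 and 101) and with DESeq2 187 (102 and 85), so the excess of higher genes was smaller with DESeq2 and absent with the passages unsummed. It was 18 with the earlier passages alone, 165 with the later passages alone and 5 with all libraries thinned to the lowest total. The earlier passages also held fewer counts than the later ones, so the numbers for single passages do not separate passage from depth. With the passages unsummed and those blocks camera kept 2 of the 5 lists, cell cycle and nuclear retained RNA.

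Pool cultures against BALF repeated the culture contrast with other cultures but the same BALF libraries, so it is not independent of mexAM against BALF. Vipr2 was at least 101-fold higher and Cyp4a12b changed by +8.26 ± 0.46, while Cd2 changed by -6.79 ± 0.40, Itgax by -3.32 ± 0.57, Chil3 by -2.15 ± 0.34 and Csf1r by -1.61 ± 0.32. Mki67 changed by +2.57 ± 0.29, and Fabp1 by +1.74 ± 0.33, a call lost with BALF of mouse 1 alone (+1.51). Siglecf was not called (+0.77 ± 0.29, adjusted p = 0.0581). Of 38 cell cycle genes 34 were higher and 0 lower (34 and 0 adjusted over the list alone), with a median of +2.51 and camera adjusted p = 2.37e-16, adjusted p = 0.248 with an estimated correlation.

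For the other called lists the numbers higher and lower in the pool cultures are followed by those adjusted over the list alone in parentheses. Higher were cholesterol (17 and 0 of 24 (18 and 0)), fatty acid oxidation (9 and 1 of 22 (12 and 1)), PPARgamma target (8 and 2 of 22 (8 and 2)) and oxidative phosphorylation genes (4 and 0 of 46 (1 and 0)). Camera gave 3.06e-08, 0.00140, 0.0267 and 0.0420, and adjusted p = 0.198, 0.290, 0.494 and 0.772 with an estimated correlation. Lower were oxidative stress (1 and 12 of 22 (1 and 12)), matrix (0 and 8 of 21 (0 and 9)), MHC class II (1 and 8 of 14 (1 and 8)) and MHC class I genes (0 and 9 of 16 (0 and 9)). Camera gave 1.55e-06, 1.68e-06, 3.1e-04 and 0.00235, and adjusted p = 0.198, 0.198, 0.290 and 0.198 with an estimated correlation. Of the dendritic cell genes, Irf8 (-3.93 ± 0.34), Cd24a (-2.81 ± 0.65) and Naaa (-1.84 ± 0.26) were also lower, while Wdfy4 (+2.15 ± 0.22) was higher. Lung epithelium (1 and 5 of 7 (1 and 5)), nuclear retained RNA (0 and 3 of 6 (0 and 4)), immediate early (1 and 8 of 26 (2 and 9)) and peritoneal macrophage genes (1 and 6 of 29 (1 and 6)) were also lower. For these camera gave 0.00124, 0.00391, 0.0311 and 0.0460, and adjusted p = 0.201, 0.198, 0.630 and 0.484 with an estimated correlation. In all 2757 genes were called, 1446 higher and 1311 lower, 2037 of them by at least 2-fold. The number was 1660 without pool 1, 1604 without pool 2 and 1403 with BALF of mouse 1 alone, and 0 of 13 called lists held with an estimated correlation.

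Pool cultures against BMDM gave Lipf, Vipr2 and Grb7 at least 213-fold, 162-fold and 144-fold higher, and Siglecf at +7.38 ± 0.41, Car4 at +7.08 ± 0.35, Fabp1 at +7.49 ± 0.45 and Pparg at +2.15 ± 0.53. The costimulatory receptor Cd28, Rnf150 and Slamf7 were at least 359-fold, 305-fold and 277-fold lower, and Itgam changed by -4.69 ± 0.42 (49.1 CPM in pool 1 and 12.9 CPM in pool 2). With the numbers adjusted over the list alone in parentheses, those higher and lower were 29 and 1 of 36 (30 and 2) for alveolar macrophage genes, 1 and 25 of 29 (1 and 26) for bone marrow macrophage and monocyte genes and 24 and 0 of 24 (24 and 0) for cholesterol genes. Their camera adjusted p were 2.56e-16, 1.81e-16 and 1.28e-15, and adjusted p = 0.00463, 0.00113 and 0.0217 with an estimated correlation. Cell cycle genes had 35 and 0 of 38 (37 and 0), with Mki67 at +3.29 ± 0.29 and camera adjusted p = 6.67e-13, adjusted p = 0.227 with an estimated correlation. In all 4575 genes were called, 2251 higher and 2324 lower, 3461 of them by at least 2-fold, and 3 of 18 called lists held with an estimated correlation, those of alveolar macrophage, bone marrow macrophage and cholesterol genes.

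Between the earlier and the later passage of the pool cultures, 5 passages apart in each pool, 1 gene was called. Rgs2, a regulator of G protein signalling (ENSMUSG00000026360, chromosome 1, 143999338 to 144004161, minus strand), was at 1183 ± 155 against 352 ± 15.9 CPM (n = 2 pools; +1.75 ± 0.27, adjusted p = 0.0244). In mexAM it was at 935 ± 247 CPM, in BALF at 740 ± 86.2, in BMDM at 608 ± 7.87 and in PLF at 608 ± 152, means between those of the 2 passages. Its call was lost without pool 1 (+1.92), without pool 2 (+1.57), with pool and mouse as blocks (+1.74, 0 genes called) and with the 7 cultured alveolar macrophage libraries alone (+1.73). At an unadjusted p under 0.05 there were 947 of 10527 genes, and DESeq2 called 32. As sets, cell cycle genes (camera adjusted p = 0.0152, adjusted p = 0.709 with an estimated correlation) and immediate early genes (camera adjusted p = 0.00436, adjusted p = 0.709 with an estimated correlation) were higher at the later passage with 0 members called. Lysosome, oxidative phosphorylation and oxidative stress genes were lower, also with 0 members called. Camera gave 0.00104, 0.00436 and 0.00436 for these, and adjusted p = 0.709 for each with an estimated correlation. Adjusted over the list alone the numbers higher and lower were 0 and 0 for the cell cycle, 3 and 0 for immediate early, 0 and 2 for lysosome, 0 and 0 for oxidative phosphorylation and 0 and 1 for oxidative stress. The cell cycle list summed to 2813 ± 393 CPM at the earlier and 4168 ± 1.60 at the later passages (SD, n = 2), against 1750 ± 283 in mexAM, 826 ± 209 in BALF, 744 ± 434 in BMDM and 619 ± 62.4 in PLF (n = 3 each). The passage changes of the pools, each from 1 library against 1, correlated at 0.12 across genes.

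**Figure D4:**
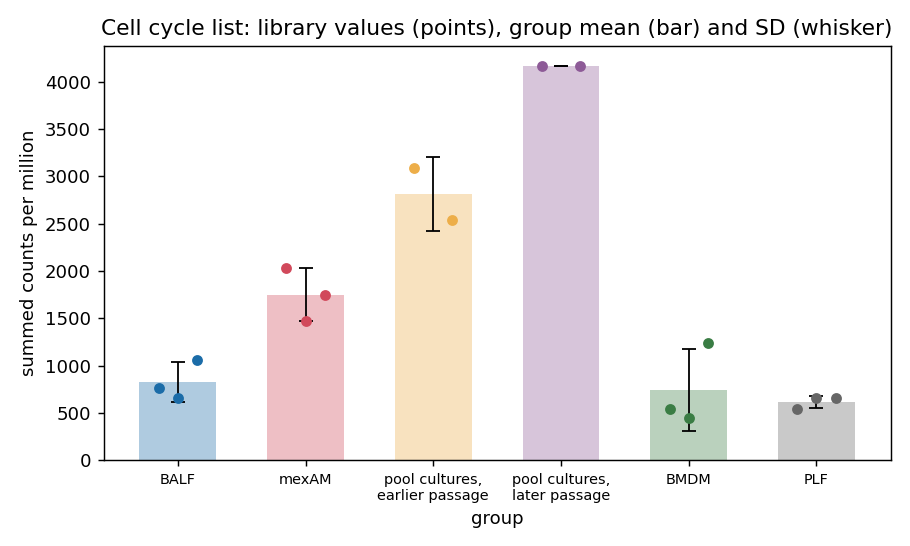
Summed CPM of the cell cycle list (vertical) by group (horizontal), with points for libraries, bars for group means and whiskers for SD. The pool cultures average 2813 and 4168 at the earlier and later passage, against 1750 in mexAM and 619 to 826 in BALF, BMDM and PLF.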

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

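The fits with BALF of mouse 1 alone, with each passage alone, with thinned libraries and without ribosomal RNA features were chosen after the data were seen, and the other alternatives before the data were examined. Alternatives were run for 23 results and for 1369 genes and lists. No named gene or called list reversed with a call, and the correlation and the similarity kept their sign. Counts of genes, overlaps and lists have no sign that could reverse. The larger direction of calls did turn in places. For pool cultures against mexAM it went from 55 higher and 19 lower to 94 and 113 with the passages unsummed. For named genes 16136 alternative values kept their side of the threshold, 638 lost the call and 22 gained one. Of 16796 such values 48 had the other sign, in 22 pairs of gene and comparison, 0 of them called. For called lists 558 values kept the call and 137 lost it.

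The counts of changed genes among BALF, PLF, BMDM and mexAM stayed within 1.5 times the values reported, with 2 exceptions. The exceptions came with BALF of mouse 1 alone, a fit with 1 BALF library in place of 3, which gave 1318 in place of 3007 for mexAM against BALF and 2429 in place of 3747 for BALF against BMDM. Without 1 library the counts were 2288 to 2738 for mexAM against BALF, 3744 to 4419 for mexAM against BMDM and 5232 to 5640 for mexAM against PLF. They were 3142 to 3573 for BALF against BMDM, 3391 to 4053 for BALF against PLF and 3004 to 3627 for PLF against BMDM. Other settings gave 2042 to 3317 for mexAM against BALF, 3210 to 5179 for mexAM against BMDM, 4285 to 6819 for mexAM against PLF, 2734 to 4206 for BALF against BMDM, 2812 to 4557 for BALF against PLF and 2597 to 4264 for PLF against BMDM.

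Pool cultures against mexAM, with 74 genes called, moved with most settings. DESeq2 called 187, no filter on low counts 380, the 4 pool libraries unsummed 207, the same with mouse and pool as blocks 198, the earlier passages alone 18, the later passages alone 165 and thinned libraries 5. Thinning removes counts, and unsummed passages count 1 pool as 2 libraries. For the other settings the cause was not tested, and the earlier passages also held fewer counts than the later ones. Without 1 pool or mexAM library the count was 6 to 99. Pool cultures against BALF (2757) gave 1403 with BALF of mouse 1 alone and 1604 to 2427 without 1 pool or BALF library, the lowest with 1 pool left. Pool cultures against BMDM (4575) gave 3266 to 4291 without 1 pool or BMDM library. Later against earlier passage (1 gene) gave 32 with DESeq2, 80 with no filter, 0 with mouse and pool as blocks, 0 with the 7 cultured alveolar macrophage libraries alone and 0 without either pool, where the cause was not tested. Against the fit of the same libraries without it, the block changed no other count of genes by more than 1.5 times.

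The correlation of the contrasts that share no library (0.582) was 0.394 with no filter, 0.606 with genes of at least 10 CPM and 0.547 to 0.561 without 1 mouse. The genes shared in direction (1481) numbered 1152 to 1647 across settings and 1225 to 1326 without 1 mouse. The similarity of mexAM to BALF minus that to BMDM (0.163) was 0.0522 with no filter, 0.207 with genes of at least 10 CPM, 0.160 without the genes of the other-cell and RNA-quality lists and 0.1555 to 0.166 without 1 mouse. Genes with few counts enter when no filter is used.

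Of the lists called by camera, an estimated correlation kept 0 of 13 for mexAM against BALF, 3 of 16 against BMDM and 9 of 21 against PLF. It kept 2 of 14 for BALF against BMDM, 7 of 18 for BALF against PLF and 5 of 16 for PLF against BMDM. For the pool cultures it kept 0 of 5 against mexAM, 0 of 13 against BALF and 3 of 18 against BMDM, and for the passages 0 of 5. Such tests allow for genes of a list moving together. Fry, directional, called 27 for mexAM against BMDM, 22 for BALF against BMDM, 28 for BALF against PLF, 28 for PLF against BMDM, 1 for pool cultures against mexAM and 0 for the passages. Elsewhere fry, directional, stayed within 1.5 times. Fry, mixed, which counts change in either direction, called 33, 39 and 38 for mexAM against BALF, BMDM and PLF, and 38, 39 and 37 for BALF against BMDM, BALF against PLF and PLF against BMDM. For pool cultures against mexAM, BALF and BMDM it called 9, 34 and 38, and for the passages 10. With the passages unsummed and the block camera called 2 lists in pool cultures against mexAM, where the cause was not tested.

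Of the genes named and called, a left-out library ended the call of 20 of 132 for mexAM against BALF, 10 of 152 against BMDM and 4 of 155 against PLF, 11 of 148 for BALF against BMDM, 6 of 150 for BALF against PLF and 19 of 144 for PLF against BMDM. For the pool cultures these were 17 of 19 against mexAM, 24 of 122 against BALF and 11 of 154 against BMDM, and for the passages 1 of 1. BALF of mouse 1 alone ended 40 of 132 calls for mexAM against BALF. At these depths and numbers of mice, changes of 1.5-fold were recovered in the simulated data for at most 6.15% of genes, so a gene that was not called is not shown to be unchanged.

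For each of the 6 comparisons of 3 libraries with 3, the 10 splits of the 6 libraries are too few for a share under 0.05, and 1 split, the real one, gave as many genes as reported. The real values and the highest of the other splits were 3007 and 0 for mexAM against BALF, 4462 and 0 for mexAM against BMDM, 5800 and 0 for mexAM against PLF, 3747 and 0 for BALF against BMDM, 4031 and 8 for BALF against PLF, and 3652 and 2 for PLF against BMDM. Each other split put both cell types into each group, so the difference between cell types entered the spread. Few calls there would follow in any case, so the splits cannot decide on chance.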

Other observations

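The tests of B cells, dendritic cells, scaling and passage number below were chosen after the result was seen, that of depth after the data were seen but before its own result, and that of single mexAM libraries before.

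MHC class II genes were lower in mexAM than in BALF. The B cell list in BALF reached at most 33.5% of the CPM that the excess would need at the ratio in PLF. This share cannot decide for the genes most lowered. H2-Ab1 and Cd74 held 211 and 132 of the 7638 CPM of the class II list in BALF. The B cell list summed to 939 ± 63.0 CPM in BALF and 886 ± 83.6 in mexAM, most of it Bhlhe41 (866 ± 54.3 and 807 ± 109). Ighm, an immunoglobulin gene, was at 0 to 3.47 CPM in BALF and 1215 to 1727 in PLF, and Cd79a had 0 counts in BALF. These B cell genes argue against B cells in the lavage as the source. The tables also argue against scaling, since the 8 genes called lower were still called with library totals alone and with RLE size factors. Dendritic cells in the lavage stay open, with 6 of 12 dendritic cell genes outside MHC class II called higher in BALF and 1 higher in mexAM. Irf8 was at 131 CPM in BALF against 9.57 in mexAM and Naaa at 291 against 80.9, while Wdfy4 was at 34.9 against 175. Fscn1 and Ccr7, also called higher in BALF, reached only 4.74 and 3.63 CPM there. Clec10a, Irf4, Cd209a and Mgl2 of the same list were at 0 CPM in BALF. A change of the macrophages themselves in culture also stays open, as an untested hypothesis. So does RNA quality, untested, since mitochondrial ribosomal RNA took 8.81% to 11.21% of counts in BALF and 5.81% to 6.79% in mexAM.

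Cell cycle genes were higher in pool cultures than in mexAM, with a median of +1.19 from sums in which the later passage weighs more. With all libraries thinned to 827791 counts the median was +1.21. Thinning keeps the expected share of each gene in its library, so this median cannot decide on depth. A single mexAM library is argued against, as the median without any 1 of them was 1.07 to 1.28. The number of passages stays open. The median between later and earlier passage was +0.50 in pool 1 and +0.57 in pool 2, each from 1 library against 1, so their spread between cultures is unknown. The list was called for passage by camera (adjusted p = 0.0152) and not with an estimated correlation (adjusted p = 0.709), with 0 members called. The passage of mexAM was not given, and a difference between pools and single mice as sources stays open, untested, as does RNA quality, since mitochondrial ribosomal RNA was also higher in the pools (9.12% to 11.05% of counts against 5.81% to 6.79%).

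The levels of some genes per library were chosen after their values were seen, although the naming rule also gives Cish. Csn2, which encodes beta casein (ENSMUSG00000063157, chromosome 5, 87692624 to 87699630, minus strand), was at 874, 511 and 133 CPM in mexAM, at 801 and 914 CPM in pool 1 and at 40.9 and 31.5 CPM in pool 2. It was at most 4.86 CPM in the libraries of BALF, BMDM and PLF, and changed by +7.57 ± 0.84 in mexAM against BALF (adjusted p = 3.67e-05). Cish, a cytokine-induced inhibitor of signalling, was at 109, 71.3 and 131 CPM in mexAM, at 30.997 to 127 CPM in the pool cultures and at 3.47 to 11.3 CPM in BALF. It changed by +3.91 ± 0.45 against BALF and by +4.56 ± 0.45 against BMDM, and stood at 23.6 to 70.7 CPM in PLF.

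Malat1, a nuclear RNA, was at 832 to 1481 CPM in the pool cultures and 3077 to 3551 CPM in mexAM (-1.43 ± 0.34, adjusted p = 0.0551, not called), and Neat1 changed by -1.70 ± 0.28, a call lost without pool 1 (-1.85) or pool 2 (-1.56), with the earlier passages alone (-1.36) and with thinned libraries (-1.49). Itgam was at 72.1 CPM in pool 1 at passage 13 and at 4.12 to 13.4 CPM in the other cultured alveolar macrophages. Of genes called with at least a 2-fold change both for mexAM against BALF and for BMDM against PLF, 7 of 22 inflammatory, 7 of 22 oxidative stress, 6 of 14 MHC class II, 6 of 26 immediate early and 4 of 20 TGFbeta responsive genes were lower in culture in both. In these lists 2 oxidative stress genes were higher in both, and 2 MHC class II and 4 immediate early genes moved in opposite directions. Of 29 bone marrow macrophage and monocyte genes 2 were lower and 2 higher in both and 4 moved in opposite directions, and 3 of 23 cholesterol genes were higher in both. BMDM and PLF differ in origin as well as in culture. Other cells differed in the same contrasts, with 19 of 19 B cell genes higher in PLF than in BMDM and 6 of 12 dendritic cell genes higher in BALF than in mexAM. A lower level of the genes of these lists, MHC class II among them, is therefore not shown to come from culture. The peritoneal list is left out here, since its genes were chosen as high in peritoneal cells.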
